A study of Mus musculus with 6 samples.

How the data were processed

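Spleen samples of imiquimod-treated mice, 3 B6.Sle1b and 3 Sle1b.IFNγR-/-, were profiled by RNA sequencing. Per the labels' protocols, RNA was extracted with TRIzol, had an A260:A280 ratio above 1.9 and an RNA integrity number above 7, and was made into cDNA libraries with the NuGEN Ovation V2 kit, an amplification kit for small amounts of RNA. Per the submitters' processing notes, CASAVA, TopHat2 2.0.9, Cufflinks 2.2.1 and build GRCm38 were used. The annotation release and the handling of reads that map to several places are not given in the sources used here. The libraries come from separate labelled samples; the labels do not state that each is a separate mouse, so p-values measure the spread between these samples.

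The deposited signal is a table of fragment counts per gene locus that the authors scaled between libraries by quartile, per the file headers and the table's name. Its 1530481 rows repeat each locus once per transcript, with 0 loci whose repeated rows disagreed, and were collapsed to 426574 loci. Of these, 44794 had a gene name and 381780 had none. In each library 99.8% of the positive values were whole multiples, within 0.01 of a step, of a single step between 0.822 and 1.198. Dividing by the step gave the fragments per library. As the remaining values kept the counts from being recovered in full, tests for counts were not used. The values were treated as scaled signal, and the design's branch for scaled values applied. A value of 3 fragments corresponds to between 2.47 and 3.59 scaled counts, and counting error is only part of the spread. Another 24 columns of per-sample values, such as estimated variances, were not used. Coordinates came from GENCODE mouse release 21 on GRCm38, matched by transcript identifier or name for 98.7% of named loci. Of the loci, 1170 carried more than 1 gene name, and 790 names occurred at more than 1 locus. The protocol's strand setting is not given, so overlapping and antisense genes are not separated.

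Named loci with a mean of at least 10 over the 6 libraries (19227) were tested on log2(value + 1) with limma 3.58.1 in R 4.3.3, with an intensity trend and genotype as the only term. A fold change on this scale understates the change of low genes. Benjamini-Hochberg adjusted p under 0.05 was the threshold. Before the data were examined, 31 gene lists were fixed, 19 of pathways and B or T cell states and 12 of other cell types and adjacent tissue. Of their 563 entries, 551 matched a locus. They were tested with camera with a preset correlation of 0.01 and with an estimated correlation, and with fry, which gave no list an adjusted p under 0.05. Isotype shares were compared with two-sided exact permutation tests in scipy 1.17.1, under python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. With 3 against 3 libraries the smallest p is 0.1.

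The genes named follow a rule fixed before the data were examined. It takes Ifngr1 and Ifngr2, and, because no gene passed, the 5 of smallest p in each direction, skipping predicted genes, clone names, pseudogenes, small RNAs and immunoglobulin or T cell receptor segments (0 skipped among lower and 6 among higher). It also takes up to 4 members of smallest p in lists that passed, up to 2 in others, and the 12 constant region genes. Genes called with the covariate, Nnt and Gm21857 were named after their values were seen.

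Alternatives fixed beforehand were median-ratio, upper-quartile and total scaling, totals without abundant genes, no low-value filter, a minimum of 50, pseudocounts of 0.5 and 10, robust limma, a replicate block, leaving out each library, another denominator for isotypes and windows of 5 and 40 Mb. Planned count tests could not apply. Scaling to ribosomal protein genes, the ribosomal or a housekeeping covariate (12 genes), windows around Ifngr2 and a test of all 152353 loci with a mean of at least 10 were added after the data were seen. The procedure was tested on simulated data made from the real means of the comparison of the 2 genotypes, over 19227 genes with 100 genes changed by 2 and 100 by 4. As deposited, 2% and 37% of them were recovered with 0 false calls. With the ribosomal covariate, 23% and 87% were recovered with 4 false calls. The simulated libraries were given each gene's real trend with the ribosomal level. Their spread was taken from the fit with that covariate. The better recovery with the covariate was therefore built in and does not speak for that fit.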

Results

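Spleen RNA was sequenced in 6 samples from mice treated with imiquimod, an agonist of the RNA sensor TLR7, 3 times a week for 4 weeks. In 3 samples the mice were B6.Sle1b, a C57BL/6 line carrying a lupus susceptibility interval. The other 3 were Sle1b.IFNγR-/-, the same line without a working interferon-γ receptor. The comparison asks which spleen transcripts of TLR7-stimulated, autoimmune-prone mice differ when interferon-γ signalling is missing, with attention to antibody-forming and germinal centre B cells. The values are scaled fragment counts per gene locus. The libraries corresponded to 5641797, 6349824 and 5531777 fragments in B6.Sle1b replicates 1 to 3 and to 5960907, 4696327 and 4394300 in Sle1b.IFNγR-/- replicates 1 to 3. Loci with a gene name held 27.0% of the values in B6.Sle1b replicate 1 and between 17.5% and 19.95% in the other 5 libraries. The median level of 30 ribosomal protein genes was 2.40 times the geometric mean of all libraries in B6.Sle1b replicate 1, 0.714 in replicate 2 and 0.949 in replicate 3. It lay between 0.820 and 0.895 in the Sle1b.IFNγR-/- libraries, so that the spread of RNA level was far wider within B6.Sle1b than within Sle1b.IFNγR-/-. A median log2 level of 12 housekeeping genes spread wider, at 1.96, -1.23 and -0.0013 in B6.Sle1b replicates 1 to 3. The ribosomal log2 level there was 1.26, -0.49 and -0.076. In Sle1b.IFNγR-/- the housekeeping level lay between -0.28 and -0.19.

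**Figure D1:**
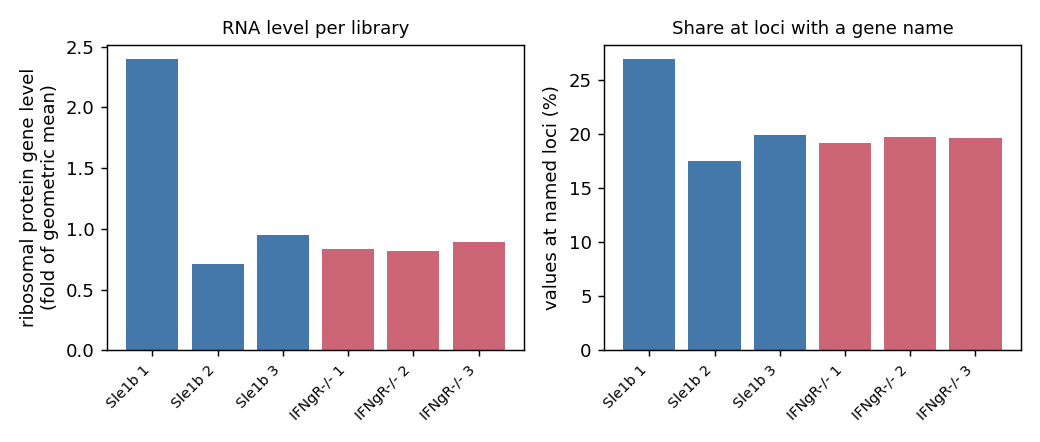
Ribosomal protein gene level (left, fold of the geometric mean of the 6 libraries) and percent of all values at loci with a gene name (right), one bar per library, blue for B6.Sle1b and red for Sle1b.IFNγR-/-. B6.Sle1b replicate 1 stands at 2.40 and 27.0%, above the other 5 libraries in both panels.

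The receptor genes were examined first. Ifngr1, the ligand-binding chain of the interferon-γ receptor (chromosome 10, 19591949 to 19610229, GRCm38), had scaled counts of 81.5, 34.5 and 63.7 in B6.Sle1b and 43.7, 21.4 and 23.96 in Sle1b.IFNγR-/-. The means were 59.9 ± 23.7 and 29.7 ± 12.2 (SD, n = 3 each), with overlapping ranges. The log2 difference was -0.98 (SE 0.41) on the log2(value + 1) scale, with a limma Benjamini-Hochberg adjusted p of 0.99976. Ifngr2, the second chain (chromosome 16, 91547072 to 91565623), lay at 11.03 ± 3.09 and 6.72 ± 2.95 (SD, n = 3 each), under the mean value of 10 needed for the test. The labels name neither the disrupted subunit nor the altered part of the gene, and a targeted gene can still be transcribed, so these levels do not check the genotype labels.

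No single gene passed the test across 19227 named loci. The gene with the smallest p was Cxcl9, a chemokine induced by interferon-γ that attracts T cells (chromosome 5, 92321347 to 92328079). Its scaled counts were 207, 46.0 and 67.5 in B6.Sle1b and 6.12, 15.7 and 7.19 in Sle1b.IFNγR-/-, a log2 difference of -3.14 (SE 0.53). The other 4 genes of smallest p with lower values were the stathmin family gene Stmn3 (44.96 ± 11.9 against 11.7 ± 1.24), 1 of 2 loci named Rps29 (57.2 ± 7.82 against 21.8 ± 6.82), the IgG3 constant region gene Ighg3 and the single-strand DNA-binding protein gene Fubp3 (45.1 ± 5.34 against 16.4 ± 6.55). With higher values in Sle1b.IFNγR-/-, they were Mid1, an X-linked ubiquitin ligase gene (29.8 ± 17.1 against 95.6 ± 27.5), the bile acid transporter gene Slc10a2 (6.08 ± 0.85 against 23.9 ± 2.03), the muscle actinin gene Actn3 (10.5 ± 1.60 against 29.5 ± 5.85), the olfactory receptor gene Olfr122 (8.75 ± 1.80 against 29.1 ± 12.7) and the other Rps29 locus (17.6 ± 22.4 against 57.6 ± 9.79). Means are given as B6.Sle1b against Sle1b.IFNγR-/- with SD, 3 libraries each. The 2 loci named Rps29 were matched to the same gene and coordinates (chromosome 12, 69157722 to 69159186) and differed in opposite directions. Reads may have been divided between them or with near-identical copies, so neither is read as a change of that gene. The limma test left 0 genes past an adjusted p of 0.05, and 596 genes (197 higher, 399 lower) had an unadjusted p under 0.05, where 961 would be reached by chance. Leaving out B6.Sle1b replicate 1 or replicate 2 gave 5 genes each, and Ighg2c and Ighg3 were in both sets.

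**Figure D2:**
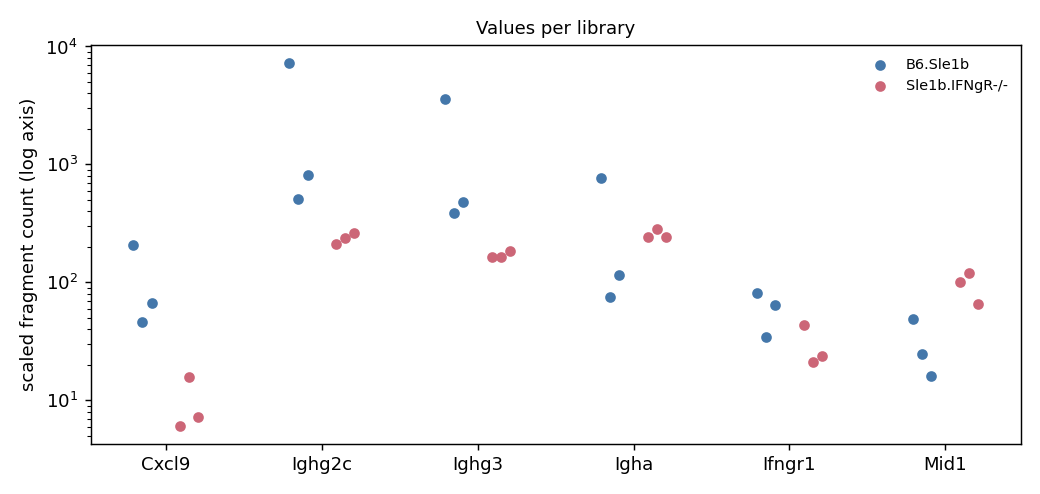
Scaled fragment counts (log axis) of 6 genes, one point per library, blue for B6.Sle1b and red for Sle1b.IFNγR-/- (n = 3 each). Cxcl9, Ighg2c and Ighg3 lie lower in every Sle1b.IFNγR-/- library and Mid1 higher, while the ranges of Igha and Ifngr1 overlap.

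The shares of the immunoglobulin heavy-chain constant regions were compared between the groups. Ighg2c, the IgG2c constant region (chromosome 12, 113285325 to 113288932), made up 30.7%, 15.7% and 16.4% of the heavy-chain constant region values in B6.Sle1b and 8.11%, 8.99% and 9.02% in Sle1b.IFNγR-/-, a difference of -12.2 percentage points. Ighg3 (chromosome 12, 113356224 to 113361232) made up 12.2% ± 2.69 against 6.24% ± 0.049 (SD, n = 3 each). Igha, the IgA constant region (chromosome 12, 113254830 to 113260236), made up 2.61% ± 0.52 against 9.44% ± 1.32, and Ighd, the IgD constant region of naive B cells, 3.28% ± 1.63 against 6.79% ± 0.57. In these 4 genes the groups did not overlap, and each reached the smallest two-sided exact permutation p that 3 against 3 libraries allow, 0.1, or 0.2 after adjustment over the 8 genes, so none could pass. The shares of Ighm (35.4% ± 10.2 against 41.2% ± 2.60), Ighg1 (8.02% ± 4.26 against 11.1% ± 0.65), Ighg2b (15.3% ± 3.74 against 12.9% ± 0.48) and Ighe (2.36% ± 1.76 against 3.60% ± 0.37) overlapped. Without B6.Sle1b replicate 1 the IgG2c difference was -7.36 points. As a share of all values of a library, Igha held 0.0133%, 0.0014% and 0.0022% in B6.Sle1b and 0.0046%, 0.0054% and 0.0046% in Sle1b.IFNγR-/-, a difference of -0.00077 percentage points that rests on B6.Sle1b replicate 1. Without that library the log2 difference of Igha was 1.44 (adjusted p = 0.015), against 0.44 with all 6 and -0.22 without B6.Sle1b replicate 2. Of all values Ighd held 0.0048% against 0.0035%, with overlap, and its log2 difference was -0.255, or 0.26 without B6.Sle1b replicate 1. The gamma constant genes are similar in sequence, and reads may have been divided among them.

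**Figure D3:**
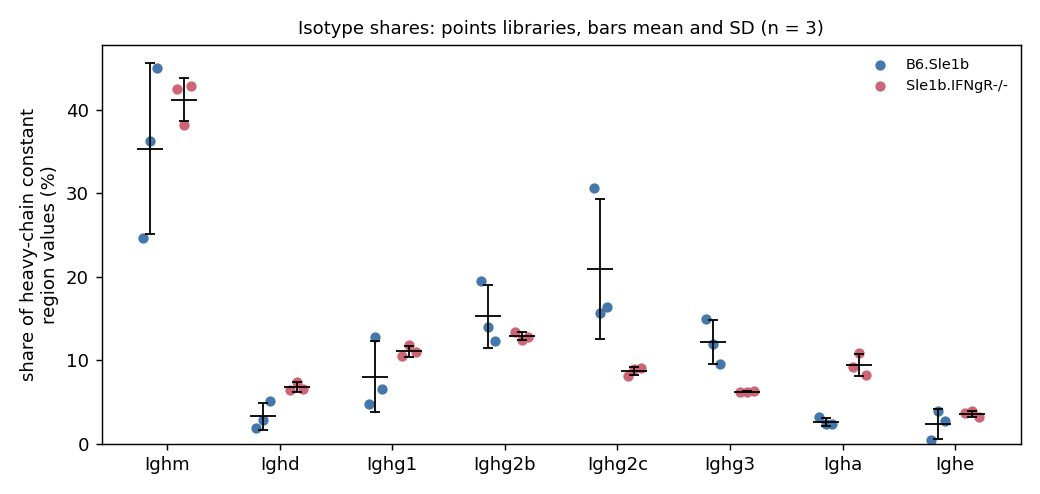
Share of each heavy-chain constant region gene among all heavy-chain constant region values (%), one point per library, with the mean and SD of 3 libraries in black, blue for B6.Sle1b and red for Sle1b.IFNγR-/-. Ighg2c and Ighg3 lie lower and Igha and Ighd higher in every Sle1b.IFNγR-/- library.

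Most interferon-γ-inducible genes had lower values in Sle1b.IFNγR-/- spleen, but the list passed only with the preset correlation. Of 30 tested members, 24 had negative and 6 positive log2 differences, with a median of -0.58, or -0.30 (adjusted p = 0.038) without B6.Sle1b replicate 1. The smallest p among them belonged to Cxcl9, Serpina3f (59.3 ± 27.8 against 26.0 ± 11.7), Tgtp2 and Zbp1. The list passed camera with a preset correlation of 0.01 (limma, adjusted p = 3.1e-05 over 31 lists) and did not with an estimated correlation (adjusted p = 0.956). The estimate for this list was 0.40, far above the preset, so the preset p overstates the evidence if that estimate holds. The same holds for the MHC, antibody-forming cell and constant region lists below. Cxcl9 alone passed when adjusted over the list alone, and 0 members passed over all genes. The genes of antigen presentation had lower medians too. For MHC class I, where H2-K1 and Psmb9 had the smallest p, 16 of 19 members were lower (median -0.35, adjusted p = 0.0021), and for MHC class II, with H2-Eb1 and Ifi30, 10 of 11 (median -0.56, adjusted p = 0.0072). Both calls were lost with an estimated correlation (0.62 and 0.81, adjusted p = 0.956) and without B6.Sle1b replicate 1 (adjusted p = 0.584 and 0.817), the library of highest RNA level. Without B6.Sle1b replicate 2 the medians were -0.80 and -1.38, and without replicate 1 -0.050 and -0.081. When values were scaled to the ribosomal protein genes the class I median became 0.11, while the median of all genes went from -0.083 to 0.36. Type I interferon-stimulated genes had a median of -0.18, with 21 of 30 members lower, and did not pass (adjusted p = 0.196). Among them Mx2, an antiviral GTPase gene, lay at 29.96 ± 8.91 and 12.3 ± 4.98.

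Markers of antibody-forming cells were lower in all 18 tested members, with a median of -0.81. The median was -0.25 (adjusted p = 0.0041) without B6.Sle1b replicate 1 and -1.29 without replicate 2. Creld2, an endoplasmic reticulum stress gene, lay at 38.9 ± 39.0 in B6.Sle1b and 3.96 ± 1.93 in Sle1b.IFNγR-/-, Derl3 at 25.7 ± 12.3 and 7.76 ± 4.04, Igj, the joining chain of IgM and IgA, at 172 ± 178 and 46.0 ± 6.17, and Prdm1, which drives plasma cell differentiation, at 70.2 ± 14.5 and 42.7 ± 7.67 (SD, n = 3 each). None of them passed over all genes or over the list alone. The list had an adjusted p of 2.0e-08 with the preset correlation and 0.956 with an estimated correlation of 0.72. The 12 immunoglobulin constant regions had a median of -0.97 (adjusted p = 3.9e-06, and 0.956 with an estimated correlation of 0.57), with Igha the only member above 0. Their median was -0.36 (adjusted p = 7.0e-05) without B6.Sle1b replicate 1 and -1.61 without replicate 2. Adjusted over the list alone, 3 passed: Ighg3, Ighg2c and Igkc, the kappa light chain. Scaled counts of Ighg2c were 7273.5, 512 and 821 against 213, 236 and 264, those of Ighg3 3553, 390 and 481 against 163, 164 and 183, and those of Igkc 9267, 677 and 1097 against 424, 357 and 461. B6.Sle1b replicate 1, whose RNA level was highest, thus carried most of the group mean in all 3. The lambda genes Iglc1 (466, 12.3 and 141 against 54.2, 64.1 and 102), Iglc2, at a locus merged with Iglj2 (59.1, 9.04 and 13.1 against 25.4, 16.9 and 1.198), and Iglc3 (191, 23.8 and 27.2 against 42.0, 21.4 and 19.2) overlapped between groups.

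Age-associated B cell markers had a median of -0.60, with 9 of 11 lower (adjusted p = 0.014), among them Zbtb32 (69.1 ± 7.90 against 40.05 ± 11.9) and Itgax (78.5 ± 18.9 against 50.9 ± 7.11). Proliferation genes had a median of -0.38 with 24 of 27 lower (adjusted p = 0.0090), among them the replication helicase gene Mcm5 (74.0 ± 47.4 against 29.9 ± 4.49). Marginal zone B cell markers went the other way, with 10 of 11 higher and a median of 0.25 (adjusted p = 0.011). The smallest p belonged to the complement receptor gene Cr2 (57.2 ± 23.6 against 99.3 ± 16.8) and to Marcks (45.9 ± 37.3 against 64.9 ± 16.2, overlapping). These 3 lists also had an adjusted p of 0.956 with an estimated correlation, which was 0.47, 0.60 and 0.20 in turn. The age-associated call was lost without B6.Sle1b replicate 1 (median -0.22, adjusted p = 0.501) or Sle1b.IFNγR-/- replicate 3 (0.148). The proliferation median became 0.15 (adjusted p = 0.628) without B6.Sle1b replicate 1 and -0.60 without replicate 2, and its call was lost with a minimum mean of 50 (adjusted p = 0.080). The marginal zone call was lost without B6.Sle1b replicate 2 (adjusted p = 0.175), Sle1b.IFNγR-/- replicate 1 (0.080) or replicate 2 (0.053), and with no low-value filter (0.054), and its median was 0.59 without B6.Sle1b replicate 1, 0.12 without replicate 2 and 0.39 without replicate 3. Germinal centre B cell markers had a median of -0.19 (12 of 16 lower, adjusted p = 0.400). Bcl6, the germinal centre transcription factor gene, had 95.8, 37.8 and 82.5 in B6.Sle1b and 35.9, 21.4 and 27.6 in Sle1b.IFNγR-/-, without overlap but not past the threshold.

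Counting germinal centre and type I interferon genes, 23 lists did not pass. Their median log2 differences were -0.35 for T follicular helper markers, -0.29 for Th1 and cytotoxic T cell genes, -0.23 for B cell markers, -0.45 for the TLR7 pathway and B cell survival factors, -0.21 for interferons and their receptors, 0.00435 for inflammatory cytokines and -0.30 for SLAM family and Sle1b interval genes. Among markers of cell types the medians were -0.071 for T cells, -0.16 for NK cells, -0.12 for neutrophils and granulocyte precursors, 0.058 for erythroid cells, -0.066 for megakaryocytes and platelets, -0.35 for monocytes, -0.00099 for red pulp macrophages, -0.14 for conventional and -0.43 for plasmacytoid dendritic cells and -0.24 for stromal and endothelial cells. Adjacent tissue gave -0.16 for pancreas and -0.33 for adipose, immediate-early and heat-shock genes -0.22 and mitochondrially encoded genes -0.10.

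With the ribosomal protein level of each library as a covariate, an alternative chosen after the data were seen, 8 genes passed limma's adjusted p of 0.05. Ighg2c fell by 1.57 (SE 0.18) on the log2 scale, Ighg3 by 1.47 (SE 0.19), Igkc by 1.18 (SE 0.17) and Cxcl9 by 2.59 (SE 0.43), with adjusted p of 4.8e-05, 0.00044, 0.0014 and 0.0074. Igha (1.33, SE 0.21), Mid1 (2.06, SE 0.35), the catalase gene Cat (1.197, SE 0.22) and 1 of the 2 Rps29 loci (3.53, SE 0.61) rose, with adjusted p of 0.0064, 0.010, 0.031 and 0.013. With the housekeeping covariate instead, 7 genes passed, 1 higher and 6 lower, so at most 1 of these 4 rises passed there. At the level of lists 7 passed with the preset correlation. Interferon-γ-inducible genes (median -0.30, 25 of 30 lower), antibody-forming cell markers (median -0.33) and immunoglobulin constant regions (median -0.40) were lower. Marginal zone B cell markers (median 0.58, 11 of 11 higher), erythroid markers (0.79, 20 of 22 higher), red pulp macrophage markers (0.28) and mitochondrially encoded genes (0.52) were higher. The mitochondrial list had 4 tested loci, and the most abundant merged mt-Nd1 and mt-Nd2 with the rRNA genes mt-Rnr1 and mt-Rnr2. Of the 8 lists that passed as deposited, 4 did not pass with the covariate: MHC class I and age-associated B cell markers (adjusted p = 0.371 each), MHC class II and proliferation (0.749 each). None of the 7 passed with an estimated correlation, where adjusted p was 0.321 or above. For interferon-γ-inducible genes, constant regions and red pulp macrophage markers the estimate was 0.011, -0.014 and -0.056, close to or under the preset. In the simulated data a list of genes all changed by 2 had a camera adjusted p of 0.084 in this setting, and 0.015 as deposited. Failing this test with the covariate therefore does not show that a list is unchanged. The covariate rests mainly on 1 library, B6.Sle1b replicate 1, and the count of genes ranged from 2 to 54 when single libraries were left out.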

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

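The fits of all loci and with the covariate, and the tests of explanations other than that on silent receptor genes, were chosen after the result was seen, though several values these tests use were planned. Loci without a gene name were not tested in the comparisons above, but entered library totals and may have entered the authors' quartile scaling. Over all 426574 loci, named or not, the third quartile lay between 14.6 and 15.6 in every library. The scale between libraries, and with it the level called RNA level here, may therefore rest largely on unnamed loci. Unnamed loci held 73.0%, 82.5% and 80.0% of the values in B6.Sle1b replicates 1 to 3. In Sle1b.IFNγR-/- replicates 1 to 3 they held 80.8%, 80.2% and 80.3%. In a limma fit of all 152353 loci, 6 passed an adjusted p of 0.05 and 2 of these had no gene name, while 6871 had an unadjusted p under 0.05, where 7618 would be reached by chance. With the ribosomal covariate 18 passed, and 10 of these had no gene name, all 10 higher in Sle1b.IFNγR-/-.

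The share at loci without a name was lowest in B6.Sle1b replicate 1 (73.0%), where the ribosomal protein level was highest. It was highest in B6.Sle1b replicate 2 (82.5%), where that level was lowest. A difference in sequencing depth would set B6.Sle1b replicate 1 apart in fragments. Its 5641797 were 1.047 times the mean of the other 5 and inside their range of 4394300 to 6349824. Genomic DNA was expected to give 1400 genes for olfactory, vomeronasal and trace-amine receptors, silent in spleen, values that scale with exonic length. Spearman's rho across these genes was 0.0963 (permutation p = 0.0003, genes not being independent replicates), under the bound of 0.2 set beforehand, and 51.3% of them were above 0 in every library. Their median value of 4.65 is near that of 3 fragments (2.47 to 3.59), so few fragments may hide a dependence on length, the bound was too strict for such genes, and DNA stays open. Of these genes 366 had a mean of at least 10. Passing the filter for the test therefore does not show that a gene is expressed in spleen. The origin of the reads at unnamed loci stays open, and other sources, such as unspliced RNA or amplification, were not tested. No biological explanation was tested.

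The lower IgG2c and IgG3 in Sle1b.IFNγR-/- were weighed against 3 explanations. A difference in RNA level alone would have left Ighg2c near 0 with the ribosomal covariate, where it was -1.57 (SE 0.18). As deposited it was -2.61, and -1.45 without B6.Sle1b replicate 1, so part of the Ighg2c difference went with that library. Reads exchanged between gamma genes would leave their sum equal. That sum differed by -17.5 points, from 56.4% ± 12.6 to 38.9% ± 0.65 (SD, n = 3), or by -10.8 points without B6.Sle1b replicate 1. Exchange alone thus does not account for the lower sum, but how that fall divides among the gamma genes stays open. Fewer antibody-secreting cells of every isotype stay open. Against them, the Igha share of heavy-chain values was 6.83 percentage points higher, and the log2 difference of Igha was 1.33 (SE 0.21, adjusted p = 0.0064) with the covariate and 1.44 (adjusted p = 0.015) without B6.Sle1b replicate 1. With them go antibody-forming cell markers (median -0.81, and -0.33 with the covariate). As deposited the Igha difference was 0.44, and -0.22 without B6.Sle1b replicate 2, so its direction depends on which library is left out. With a covariate Igha was called in 10 of 14 settings. An effect of the missing receptor on class switching, the difference the design names, also stays open and was not tested.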

How the results depend on the processing

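The settings with a covariate, ribosomal scaling or all loci were chosen after the data were seen. Over 35 results with a test and 563 alternative values, 516 kept direction and side of the threshold, though no isotype share could pass it. Every single gene counted had an adjusted p of at least 0.99976 as deposited. Staying on that side was likely beforehand, so this count is no measure of robustness. Of 52 alternative counts of genes or lists, 40 stayed within 1.5 times the count reported. The 0 genes called became 3 with ribosomal scaling, 8 with the ribosomal covariate and 6 over all loci, and from 0 to 5 with a library left out (5 without B6.Sle1b replicate 1 and 5 without replicate 2). The 8 genes of the covariate fit became 18 over all loci and 2 to 54 with a library left out (54 without B6.Sle1b replicate 3, 3 without replicate 2, 2 without Sle1b.IFNγR-/- replicate 1 and 5 without replicate 2). The housekeeping covariate gave 7, with 1 higher and 6 lower, against 4 and 4 with ribosomal protein genes. Ighg2c was called in 14 of 14 covariate settings, Ighg3 in 13, Igkc and Mid1 in 12, Igha and Cxcl9 in 10 and Cat in 7. The Rps29 locus was called in 9 of the 13 settings that tested it. The 8 gene lists became 0 with an estimated correlation and ranged from 7 to 17 with a library left out (17 without B6.Sle1b replicate 2). As deposited 1 was up and 7 down, and without B6.Sle1b replicate 1 they were 4 up and 3 down. The replicate block left 0 genes called, 9 lists and 7 covariate genes. With group means removed, correlations of same-numbered libraries were 0.012, -0.027 and -0.011, so the numbers do not pair the samples. The Ifngr1 difference and the IgG2c share kept their direction under every alternative run.

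Directions turned as follows. Ribosomal scaling moved the median of all genes from -0.083 to 0.36, so a turn there says little. Ighd reached 0.21 with ribosomal scaling, 0.26 with the covariate, and from -0.87 to 0.26 with a library left out. Igha ranged from -0.22 to 1.44 with a library left out. Ighe was 0.14 with ribosomal scaling. Iglc1 was 0.055 with ribosomal scaling and 0.77 with the covariate. With a library left out Iglc1 ranged from -1.84 to 0.72, Iglc2 from -1.71 to 0.087 and Iglc3 from -1.45 to 0.021. With ribosomal scaling the MHC class I median was 0.11 and the proliferation median 0.085, and both lists passed as lower than other genes (adjusted p = 0.00079 and 0.0033), but not with an estimated correlation (0.159 and 0.115). The proliferation median was 0.14 with the covariate and from -0.60 to 0.15 with a library left out. Of all values of a library, Igha differed by -0.00077, resting on B6.Sle1b replicate 1, and Ighd by -0.0013 percentage points. At 4394300 to 6349824 fragments per library, 73.0% to 82.5% of the values outside named loci, low genes are measured by few fragments.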

Other observations

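The tests of splits, of the 3 loci named below, of loci near Ifngr2 and of the covariate were chosen after the results were seen. Erythroid genes moved with the covariate: Slc4a1, the red cell anion exchanger gene, had 578, 51.0 and 124 in B6.Sle1b and 228, 189 and 146 in Sle1b.IFNγR-/-, and Hba-a1, an alpha-globin gene, 514, 46.0 and 106 against 196, 160 and 126. Of 22 tested erythroid members 7 passed with the covariate when adjusted over the list alone, but as deposited the list median was 0.058.

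Nnt, a mitochondrial transhydrogenase gene on chromosome 13 (45.9, 37.8 and 41.2 against 15.7, 13.5 and 19.2), Mid1 on chromosome X and Gm21857 at a locus on chromosome Y (4.78, 1.64 and 0.94 against 30.6, 25.3 and 15.1) differed without overlap. They were chosen after their values were seen, and none passed as deposited. The loci on chromosomes X and Y leave open whether the groups differ in sex, which was not tested. Of 19227 tested loci 1672 (8.7%) did not overlap, where chance gives 10%, so lack of overlap alone is no evidence of a difference. The labels name no subunit, but 0 of the 3 lie on chromosome 10 or 16, which hold Ifngr1 and Ifngr2, so DNA flanking either gene does not account for them. Within 20 Mb of Ifngr1, 5 of 151 loci had an unadjusted p under 0.05, an odds ratio of 1.07 (95% interval 0.34 to 2.57, Fisher's exact p = 0.812). Within 5 Mb it was 3 of 47, an odds ratio of 2.14 (Fisher's exact p = 0.178), or 2.17 (Fisher's exact p = 0.096) with the covariate, and within 20 Mb of Ifngr2 it was 1.54 (Fisher's exact p = 0.297). Marcks (within 20 Mb, with the covariate) and Prdm1 (within 40 Mb, as deposited) were among loci near Ifngr1 with an unadjusted p under 0.05. With so few loci and no subunit named, flanking DNA near either receptor gene cannot be told apart from none.

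The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. As deposited, the real split called 0 genes and the highest other 0, and with 0 called the comparison over 10 splits could have no other outcome and says nothing. With the covariate the real split called 8 genes and the highest other 0, so 1 split gave as many. For lists as deposited the real split gave 8 and the highest other 17, with 7 splits as large, and the 6 splits with B6.Sle1b replicates 1 and 2 on opposite sides gave 9 to 17. The 3 other splits with them on one side gave 0 to 2. These libraries have the highest and lowest ribosomal protein level, which points to a structure of the samples. For lists with the covariate the real split gave 7 and the highest other 3, again 1 split as large.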
